A study of Homo sapiens with 4 samples.

How the data were processed

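Polyadenylated RNA of NB4 cells was sequenced in 4 libraries, 2 from cells transfected with a negative control precursor microRNA and 2 from cells transfected with the miR-125b precursor. Per the labels' protocols, each condition was transfected independently for each of its 2 libraries, so the replicates are separate transfections of a single cell line. The authors deposited 1 table per library with 26173 rows, each a RefSeq transcript with its exons and summed exon length. The deposited values are RPKM, reads scaled to exon length and to the library's total, as the values themselves show, although the tables are titled as gene counts. The genome build is hg18, per the submitters' processing notes. The aligner, the counting rule, the filters and the handling of strand are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies such as ribosomal protein pseudogenes therefore cannot be told apart.

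The depth was read from the values. Multiplied by exon length, between 81.2% and 82.2% of the values above 0 in a library came out as whole multiples of a single step within 0.01 reads, which gives the number of reads the authors scaled to: 1703626 in control replicate 1, 6023840 in control replicate 2, 6063001 in miR-125b replicate 1 and 7141703 in miR-125b replicate 2. The deepest library held 4.19 times the reads of the shallowest. The remaining values were not whole, so the fold changes were fitted on RPKM and not on the recovered reads. These reads served for the filter, the choice of a row per gene, a description of depth and a comparison of replicates. They also served for the simulated reads and for an alternative test. Counting error alone is largest in control replicate 1, where 1 RPKM stands for 1.70 reads per kilobase.

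Rows were named by their accession where possible (24829 rows), otherwise by symbol (767) or older symbol (335), and 242 rows were not matched. In 41 rows the deposited name was a number. Several transcript rows of a gene share reads, so the row with the most recovered reads stood for its gene, which left 21138 genes. Genes entered the test when at least 2 libraries reached the equivalent of 10 reads at the median depth and the total was at least 15 reads, which kept 11122 genes. The test had been planned on counts. Because the values are RPKM, miR-125b was compared with control by limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a mean-variance trend and robust moderation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change on this scale understates the change of weakly expressed genes. Errors of RPKM means are SDs over the 2 libraries of a group. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

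Before the data were examined, 30 gene lists were fixed, of which 25 had at least 3 tested members. They were tested with camera in limma, two-sided, at a preset correlation of 0.01 between genes, adjusted over the 25 lists. The genes to be named were fixed as the largest changes past the threshold or, if none passed, the 10 genes with the lowest p in each direction, with the 4 members of lowest p in each described list, ABTB1, CBFB, BAK1, the host transcripts of miR-125b and the 5 genes of highest mean level. Some of these genes and 2 of the tested lists are not reported here. Matches to the miR-125b seed were searched in the longest 3' UTR of each gene in GENCODE 29, which covered 10622 of the 11122 tested genes (95.5%). Seed site genes were tested with camera, and adjusted over 4 definitions of a site (a choice made after seeing the data). Each 7-mer was ranked by a z score, after a linear trend on log 3' UTR length and GC content was removed. The z score is the difference in mean log2 fold change between genes with and without the 7-mer, divided by its standard error over genes.

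Per the file headers, the replicate numbers mark a shared batch 1 and batch 2, so they pair the libraries. The headers of all 4 libraries also carry the letters RA, whose meaning is not given in the sources used here. Deviations of same-numbered libraries from their group means correlated across genes with r = 0.391, and with r = 0.211 after the correction described next. The comparison had been fixed without a replicate block. The fit with the block is given where it changes a call. Libraries differed in how their values followed transcript GC content, so a correction was added after seeing the data: each library's loess trend (span 0.3) on GC content and log exon length was removed. GC content was known for 11048 of the tested genes (99.3%). Replicates were not copies of each other: the chi-square per degree of freedom of the recovered reads was 4.22 between the control libraries and 6.06 between the miR-125b libraries. The SD over genes of the log2 difference ran the other way, 0.369 between the control and 0.267 between the miR-125b libraries. Both measures depend on depth, so they do not rank the groups by replicate agreement.

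The fits were tested on simulated reads for 11048 genes with the real depths, in 10 runs with 200 genes changed. The changed genes were drawn from those with over 10 expected reads in the shallowest library, so the recovery does not cover weaker genes. They were divided evenly between 2-fold and 4-fold changes, up and down. The adjustment loosens as more genes pass, so the recovery of 2-fold changes depends on the 4-fold changes beside them. It does not give the share of 2-fold changes that would be called in the real libraries. Apart from the GC trends no shift shared by a batch was simulated, although same-numbered libraries correlated with r = 0.211 after the correction. For control against miR-125b with the libraries' GC trends included, the unblocked fit recovered 62.5% of the 2-fold and 98.3% of the 4-fold changes and called on average 13.1 unchanged genes. The blocked fit recovered 74.2% and 98.6% and called on average 133.2 unchanged genes, at most 448 in a run, and with no gene changed 8.4 on average and at most 54. With the correction, the blocked fit called on average 15.1 unchanged genes and the unblocked fit 5.5. limma-voom recovered 82.4% and 99.7% and called on average 49 unchanged genes, and with no gene changed it called on average 7 and at most 26. In simulated values for 10622 genes, CTCAGGG ranked first of all 7-mers when its genes were lowered by 0.05. With no decrease its percentile ran from 2.08 to 96.9. These values were drawn independently, without GC trends, and no decrease below 0.05 was simulated. The check therefore does not cover a difference as small as the -0.021 found after the correction. Alternatives covered median-of-ratios size factors, quantile normalization, pseudocounts of 0.1 and 5, no filter, a stricter filter of 20 reads, limma-voom on the recovered reads, the sum of a gene's rows, each library left out, the replicate block and the correction.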

Results

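NB4 is a human acute promyelocytic leukaemia cell line, arrested at the promyelocyte stage of granulocyte development. The comparison asked how its mRNA levels differ after transfection of the miR-125b precursor, a small synthetic RNA that the cell processes to the microRNA, from those after a negative control precursor. Each group held 2 libraries of polyadenylated RNA. Depth ranged from 1703626 reads in control replicate 1 to 7141703 in miR-125b replicate 2, and 10461 to 10694 genes per library reached 1 RPKM. The transcripts with the highest mean levels were the noncoding RNA SNHG29 (8518 RPKM), RPS24 (5655 RPKM), MPO, the granule enzyme myeloperoxidase (4914 RPKM), RPS6 (3154 RPKM) and RPLP1 (2315 RPKM). Mature miR-125b is too short for such libraries, so they do not show its level. Its host transcripts MIR100HG and MIR99AHG were listed at 0 in all 4 libraries.

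The genes with the lowest p among those higher after miR-125b included QSOX1, a sulfhydryl oxidase, at 30.4 ± 1.36 RPKM (SD, n = 2) in control and 60.6 ± 1.57 RPKM (SD, n = 2) in miR-125b libraries. CLEC11A, a secreted growth factor of blood progenitors, had 182 ± 8.16 and 374 ± 67.7 RPKM (SD, n = 2 each). TMEM160, BST2, AOC1, SCAND1, MFAP4, PRSS57, CXCL10 and CYBA completed the 10, with log2 fold changes from 0.88 for CYBA to 1.28 for CXCL10. CXCL10 rested on 1 read in its shallowest library. Among those lower, PCTP, a phosphatidylcholine transfer protein, had 11.8 ± 1.13 RPKM in control and 4.08 ± 0.13 RPKM in miR-125b libraries (SD, n = 2 each). CYBB, the catalytic subunit of the phagocyte NADPH oxidase, had 32.2 ± 4.03 and 13.9 ± 1.23 RPKM, while its partner subunit CYBA had 68.8 ± 9.19 and 127.4 ± 12.7 RPKM. Their log2 fold changes of -1.16 and 0.88 were -0.96 and 0.32 after the correction for GC content and length, CYBA being GC-rich (69.9%). ADGRE2, an adhesion receptor of myeloid cells, had 48.8 ± 0.072 and 26.3 ± 0.86 RPKM. BIN2, SDC2, HFE, S100A9, TNFRSF10B, STEAP1 and GBP2 completed this set, with log2 fold changes from -1.27 for SDC2 to -0.82 for BIN2. S100A9, STEAP1 and HFE had at most 4.07 RPKM in any library.

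**Figure D1:**
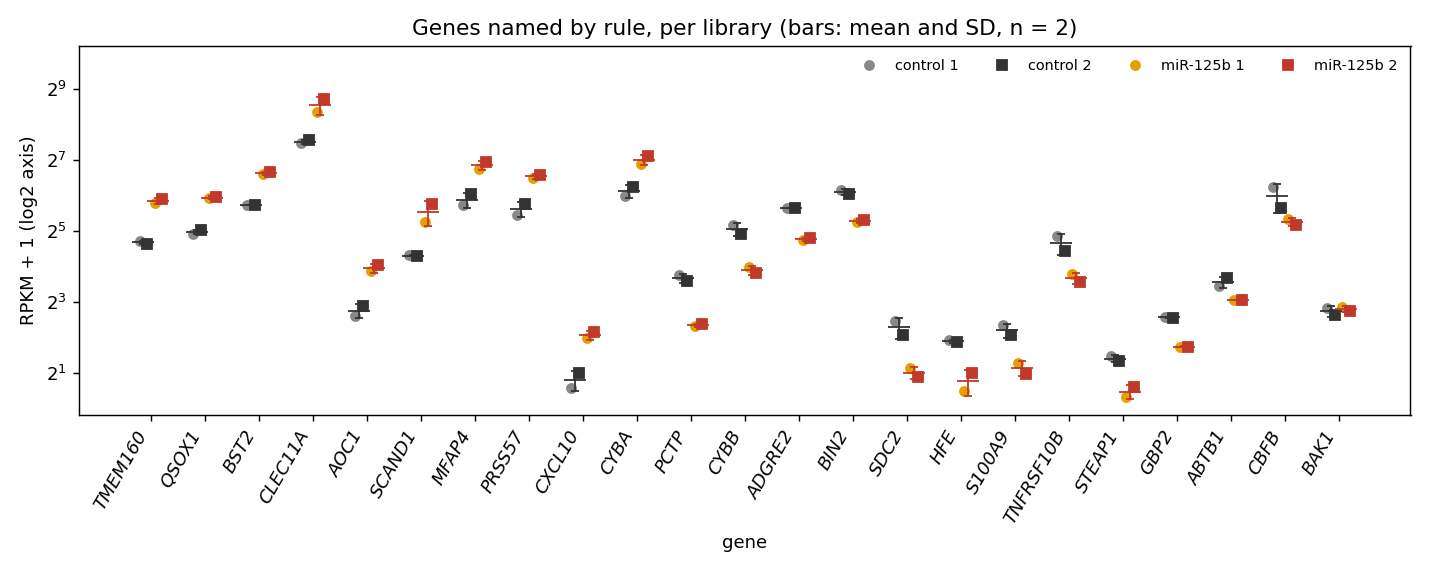
RPKM + 1 on a log2 axis for each gene named by rule, with a point per library and bars for the mean and SD of the 2 libraries of a group. Both miR-125b libraries lie above both control libraries for TMEM160 to CYBA and below them for PCTP to GBP2, although no gene passed the adjusted threshold.

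None of these genes passed the threshold: limma called 0 of 11122 genes, with a lowest adjusted p of 0.392, while 1381 genes had an unadjusted p under 0.05, 784 of them higher and 597 lower. limma-voom called 4 genes (QSOX1 and CLEC11A higher, CYBB and ADGRE2 lower), against an average of 7 in simulated reads with the libraries' GC trends and no gene changed. With the replicate block limma called 1429 genes, 773 higher and 656 lower, all 20 genes above among them, with adjusted p from 0.00038 to 0.0173. Of the 1429, 1421 could be tested with the GC and length correction added to the block, and none was called there: 0 of 11048 genes passed, and the lowest adjusted p was 0.107. In these fits PCTP went from -1.33 ± 0.15 with the block to -1.27 ± 0.14 (SE) with block and correction, ADGRE2 from -0.87 ± 0.10 to -0.85 ± 0.091, and QSOX1 from 0.97 ± 0.098 to 0.87 ± 0.083. Their folds and errors were little moved, but the moderated test had a median of 5.49 degrees of freedom with block and correction against 11.2 with the block, which raises the p of a given ratio of fold to error. The folds of the GC-rich genes TMEM160, CLEC11A and PRSS57 went from 1.17, 1.03 and 0.93 to 0.53, 0.56 and 0.45. Without control replicate 2 the count was 2149, and without control replicate 1 it was 101. The GC content of transcripts moved with the groups: log2 fold changes correlated with it across genes, which are not independent replicates, with r = 0.637.

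**Figure D2:**
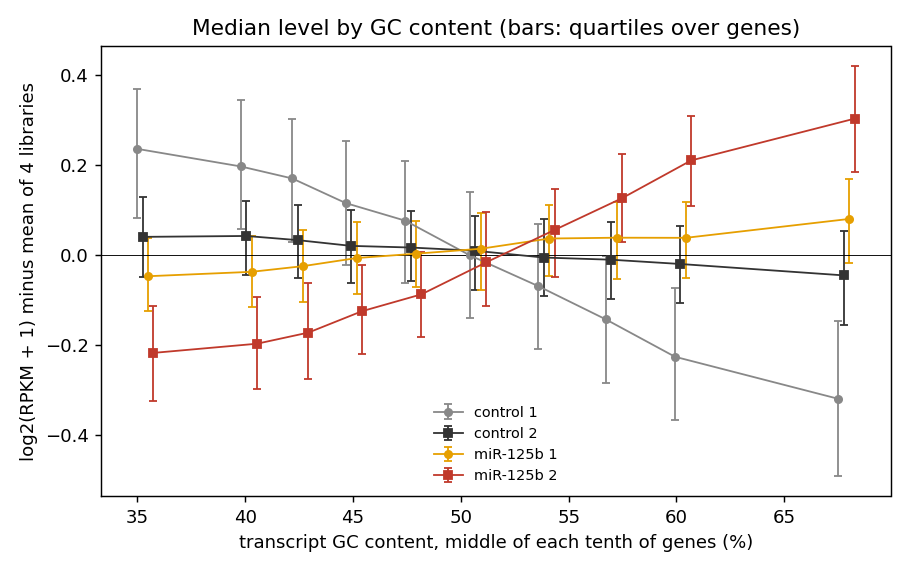
Median log2(RPKM + 1) of each library, relative to the mean of the 4 libraries, over 10 equal bins of the tested genes by transcript GC content, with bars for quartiles over genes. In the bin of highest GC content the medians run from -0.32 in control replicate 1 to 0.30 in miR-125b replicate 2, and the 2 libraries of a group differ from each other.

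ABTB1 and CBFB, which the study's authors have described as miR-125b targets, possibly from these libraries, both had lower means after miR-125b. ABTB1 (NM_172028, chromosome 3, 128874471 to 128882453 on the plus strand in hg18), an ankyrin and BTB domain protein, had 10.8 ± 1.28 RPKM in control and 7.30 ± 0.024 RPKM in miR-125b libraries (SD, n = 2 each). CBFB (NM_001755, chromosome 16, 65620551 to 65692459 on the plus strand in hg18), the partner of the RUNX transcription factors, had 61.9 ± 17.4 and 37.4 ± 3.08 RPKM. Their log2 fold changes were -0.50 ± 0.17 and -0.69 ± 0.21 (SE), and after the correction -0.81 ± 0.13 and -0.47 ± 0.15 (SE). Both were called when adjusted over the list alone and neither over all genes tested by limma (adjusted p = 0.392 for each). Because the list may come from these samples, the first is not independent evidence. With the replicate block limma gave adjusted p = 0.0444 for ABTB1 and 0.01 for CBFB, and with block and correction 0.190 and 0.279. The annotated 3' UTR of ABTB1 held an 8mer match to the seed, and that of CBFB a 7mer-A1 match. BAK1, a proapoptotic BCL2 family member whose 3' UTR held an 8mer match, had a log2 fold change of 0.07 ± 0.18 (SE), which was -0.14 after the correction and -0.041 without control replicate 2.

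The 35 tested genes of the list of published miR-125b targets had a median log2 fold change of -0.09, with 13 above 0, and did not stand apart (camera in limma, adjusted p = 0.716). The median was -0.13 without control replicate 1 (adjusted p = 0.0933), -0.010 without control replicate 2 (adjusted p = 0.983) and -0.05 without miR-125b replicate 1 (adjusted p = 0.876). After the correction the median was -0.11 and the list passed (adjusted p = 0.0446, and 0.0312 with the block). It did not pass with an estimated correlation (adjusted p = 0.879 with an estimated correlation). The list had an estimated correlation of 9.55e-05, below the preset 0.01, so correlation between members does not account for that loss. Its member with the lowest p was MCL1, an antiapoptotic protein, at 75.4 ± 7.18 and 52.2 ± 5.72 RPKM (SD, n = 2 each), followed by LIN28B, MAPK14 and PPP2CA with log2 fold changes of -0.44, -0.24 and -0.40. Of these limma called MCL1 (adjusted p = 0.00932) and PPP2CA (0.0268) with the replicate block, and neither with block and correction, where MCL1 was at -0.74 ± 0.076 (SE) against -0.52 ± 0.091 with the block, and PPP2CA at -0.19 ± 0.084 against -0.40 ± 0.098.

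Genes with a 7mer or 8mer match to the seed in the 3' UTR did not stand apart from all genes without a match, but after the correction they had a lower mean than genes matched on 3' UTR length and GC content. The median log2 fold change of 2643 genes with a site exceeded that of 6579 genes without a 6mer match by 0.05 (camera in limma, adjusted p = 0.272 over 4 site definitions). Restricted to 7mer-m8 and 8mer sites the difference was 0.09, higher with a site, which passed before that adjustment and not after it (camera in limma, adjusted p = 0.143). After the correction these differences were 0.0065 and 0.0046 (adjusted p = 0.906 for both). Without control replicate 1 the difference for all sites was -0.0011. Against genes matched on 3' UTR length and GC content, the mean of genes with a site differed by -0.016 (permutation test over genes, two-sided, p = 0.0633). After the correction the difference was -0.022 (permutation p = 0.00739), and -0.031 for 8mer sites alone (permutation p = 0.00772). This permutation takes genes as units, which are not independent replicates, so its p does not measure the spread between transfections. CTCAGGG, the match to seed positions 2 to 8, ranked 214 of 16377 7-mers from the lowest z score, and 2 of 16377 after the correction. Its corrected difference in means was -0.021 over 1777 genes. Rarer 7-mers could have a larger difference at a later rank, such as TACGGCG at -0.118 in 33 genes. TCAGGGA ranked 586, and 20 after the correction, but 8 without control replicate 1 and 5133 without control replicate 2. The percentile of CTCAGGG was 4.85 without control replicate 2, 9.70 without miR-125b replicate 1 and 0.287 without miR-125b replicate 2.

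Interferon response genes were higher after miR-125b as a set. Of 36 tested members, 35 had a log2 fold change above 0, with a median of 0.58, and the list passed (camera in limma, adjusted p = 6.77e-09). The call was lost with an estimated correlation, a setting in which every tested list had adjusted p = 0.985 (camera in limma). The estimated correlation between members of the interferon list was 0.556, the highest of the tested lists and above the preset value. BST2, which tethers budding virions, had 52.2 ± 0.44 RPKM in control and 97.9 ± 3.06 RPKM in miR-125b libraries (SD, n = 2 each). IFI6 had 29.2 ± 17.7 and 149.0 ± 117.8 RPKM, and UBE2L6, the conjugating enzyme for ISG15, 13.7 ± 0.38 and 25.9 ± 7.80 RPKM. The exception was GBP2, a guanylate binding protein, at 4.92 ± 0.081 and 2.34 ± 0.022 RPKM. None passed over all genes without the block, 1 higher and 1 lower passed when adjusted over the list alone, and 12 higher and 1 lower were called with the replicate block, the 4 named here among them (adjusted p from 0.00038 to 0.0173), and none with block and correction, where BST2, IFI6, UBE2L6 and GBP2 had log2 fold changes of 0.72, 2.03, 0.69 and -0.74, from 0.89, 2.19, 0.84 and -0.83. The set was higher by a median of 0.29 in batch 1 and of 0.84 in batch 2, and without miR-125b replicate 2 its median was 0.19 (adjusted p = 3.19e-05).

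**Figure D3:**
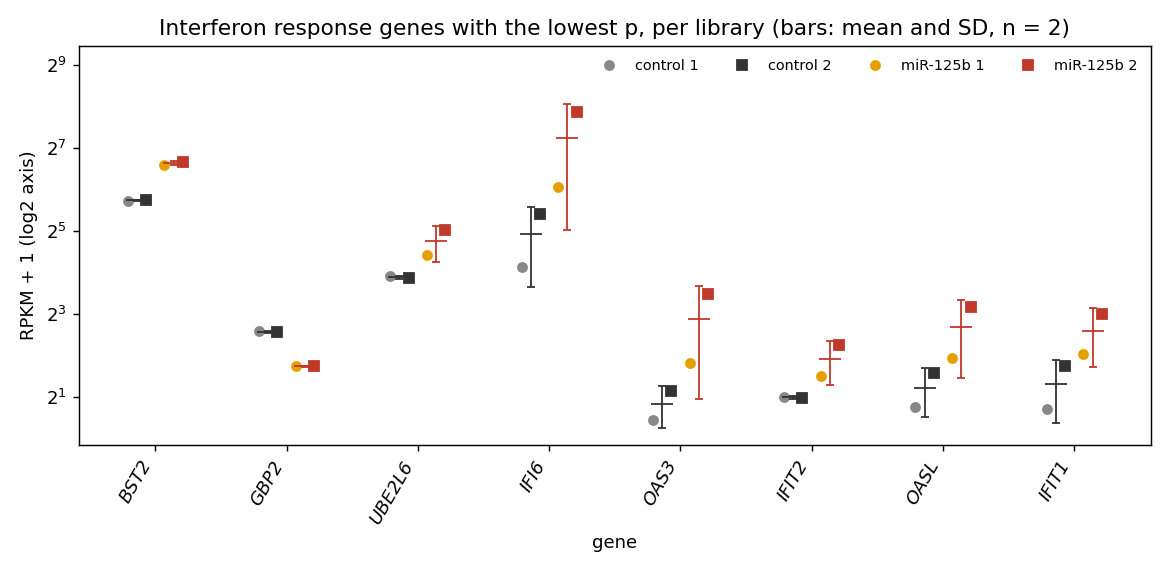
RPKM + 1 on a log2 axis for the 8 interferon response genes with the lowest p, with a point per library and bars for the mean and SD of the 2 libraries of a group. miR-125b replicate 2 lies above miR-125b replicate 1 for IFI6, OAS3 and OASL, and GBP2 is lower in both miR-125b libraries.

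Primary granule and promyelocyte genes were also higher as a set, with a median log2 fold change of 0.22 over 21 tested genes (camera in limma, adjusted p = 0.0267, and 0.0163 with the block). The call was lost with an estimated correlation (adjusted p = 0.985 with an estimated correlation), without control replicate 2 (adjusted p = 0.637), without miR-125b replicate 1 (adjusted p = 0.133) and after the correction (median 0.12, adjusted p = 0.123, or 0.0498 with the block). Of its members 13 had a fold change above 0. Adjusted over the list alone 7 were called higher and 2 lower, against 0 over all genes tested, and 9 higher and 1 lower with the replicate block, the 4 named here among them (adjusted p from 0.00056 to 0.005), but none with block and correction. The serine proteases PRSS57 and CTSG had 48.0 ± 7.22 and 209 ± 36.2 RPKM in control, and 92.0 ± 3.91 and 349 ± 32.0 RPKM in miR-125b libraries (SD, n = 2 each). CST7 and AZU1 had log2 fold changes of 0.61 and 0.86, and after the correction PRSS57, CTSG, CST7 and AZU1 were at 0.45, 0.58, 0.44 and 0.38. Mature neutrophil and monocyte genes (24 tested) went both ways, with a median of 0.04 (adjusted p = 0.716), or -0.061 after the correction. Adjusted over the list alone 2 were called higher and 2 lower, and with the replicate block 5 higher and 3 lower. Beside CYBB and CYBA, S100A9 had a log2 fold change of -1.07 and CSF3R, the G-CSF receptor, of 0.71, and these 4 were called with the block (adjusted p from 0.00056 to 0.0106). After the correction S100A9 was at -1.23 and CSF3R at 0.44, and neither was called. Retinoic acid response genes (10 tested) had a median of 0.33 (adjusted p = 0.0789), which passed with the replicate block (0.0257), without control replicate 2 (0.0268) and without miR-125b replicate 1 (0.0166), and not with block and correction (0.109). Its median was 0.15 without control replicate 1 and 0.14 after the correction, and the list had adjusted p = 0.985 with an estimated correlation. Of the 10 members 8 had a fold change above 0, and 3 higher and 1 lower had an unadjusted p under 0.05 (limma). CEBPE, UBA7 and PML had log2 fold changes of 0.53, 0.55 and 0.88, and with the block CEBPE (adjusted p = 0.0116) and PML (0.00967) were called. After the correction these 3 were at 0.19, 0.36 and 0.55. The headers of all 4 libraries carry the letters RA, whose meaning is not given in the sources used here.

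Lists for cell death did not stand apart. The BCL2 family (16 tested) had a median of -0.07 (adjusted p = 0.836), with MCL1 at -0.52, BCL2A1 at -0.51, BAD at 0.56 and BCL2L1 at 0.35. TNFRSF10B, the TRAIL receptor DR5 and among the 10 lower genes above, had 24.3 ± 5.14 RPKM in control and 11.7 ± 1.38 RPKM in miR-125b libraries (SD, n = 2 each). Caspases and apoptosis execution genes (24 tested) had a median of -0.05 (adjusted p = 0.969), with APAF1 at -0.59, TRADD at 0.59 and HTRA2 at 0.38. Of these genes MCL1 (adjusted p = 0.00932), BAD (0.0209), TNFRSF10B (0.00219) and APAF1 (0.0114) were called with the replicate block, and none with block and correction. The correction took MCL1 to -0.74 and TNFRSF10B from -0.98 to -1.03, APAF1 to -0.40 and BAD to 0.14.

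Cell cycle and growth lists did not pass. S phase and DNA replication genes (46 tested) had a median of -0.03 (adjusted p = 0.969), with TK1 at 0.57, MCM5 at 0.49, CCNE1 at -0.50 and POLD2 at 0.33. G2/M and mitosis genes (44 tested) had a median of -0.10 (adjusted p = 0.711), with CDC20 and PLK1 at 0.53 each, CDK1 at -0.56 and UBE2S at 0.50. CDK inhibitors and G1 regulators (24 tested) had a median of -0.04 (adjusted p = 0.982), with CDKN1C at 0.72, RB1 at -0.35, CDKN2C at 0.37 and E2F4 at 0.35. Ribosome biogenesis genes (32 tested) had a median of -0.02 (adjusted p = 0.968), with CAD at 0.47, NPM1 at 0.25, BOP1 at 0.38 and GNL3 at -0.31. Cytoplasmic ribosomal proteins (71 tested), whose reads can be shared with pseudogenes, had a median of -0.05 (adjusted p = 0.880), with RPL29 at 0.73, RPS15 at 0.45, RPS24 at -0.32 and RPS13 at -0.41. With the replicate block limma called 6 S phase genes higher and 2 lower, and 10 ribosomal protein genes higher and 12 lower. Of the members named here it called TK1, MCM5, POLD2, CDC20, PLK1, CDK1, E2F4, CAD, NPM1, GNL3 and the 4 ribosomal proteins (adjusted p from 0.00138 to 0.0405), and none with block and correction. The corrected folds of these genes ran from smaller, such as POLD2 at 0.096 and RPS15 at 0.13, to little moved, such as RPS24 at -0.28 and RPS13 at -0.38, and larger for NPM1 at 0.43. The mean and the direction of the test of the caspase, CDK inhibitor and ribosome biogenesis lists had the opposite sign to their median. With median-of-ratios size factors the medians of the S phase and ribosome biogenesis lists were above 0, at 0.0018 and 0.013, and after the correction those of the S phase and G2/M lists were 0.019 and 0.029.

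**Figure D4:**
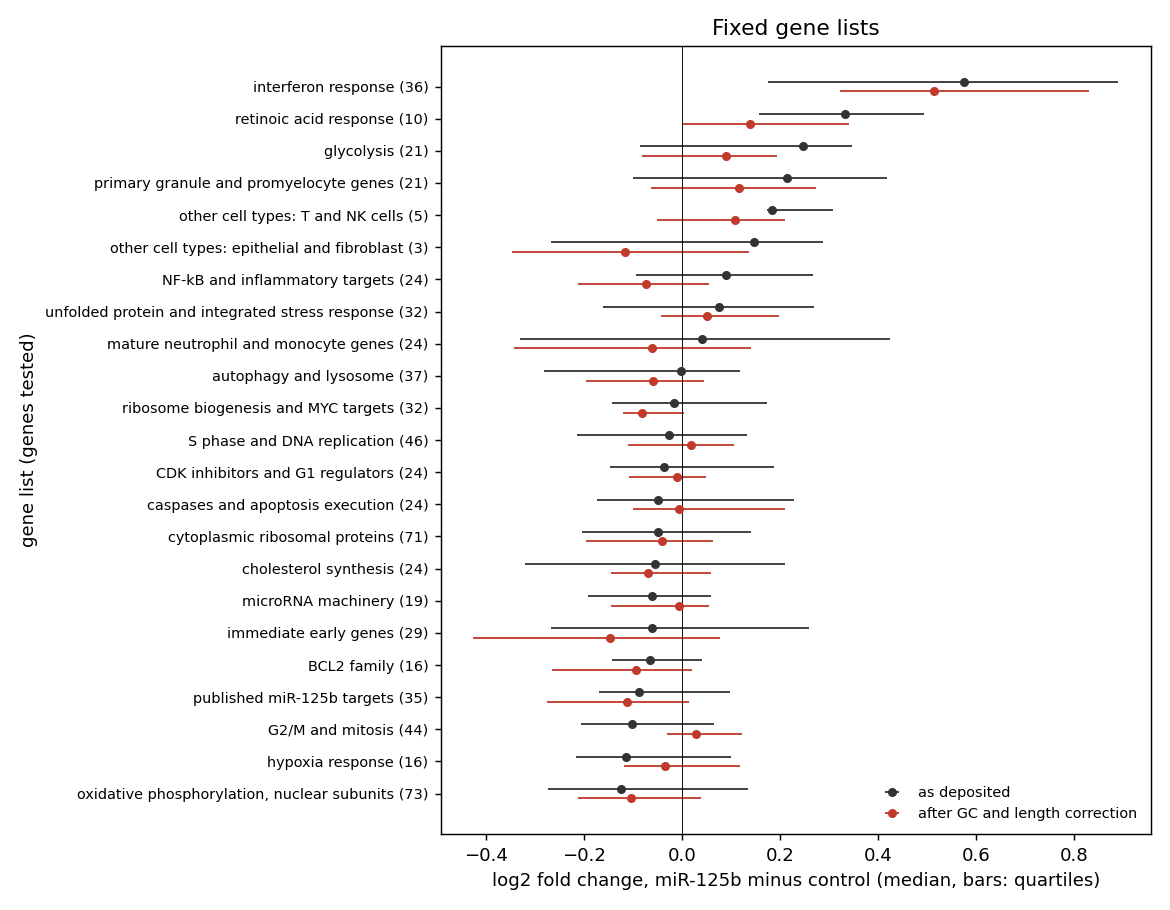
Median log2 fold change, miR-125b minus control, of the 23 gene lists reported here with at least 3 tested members, with bars for quartiles over genes, as deposited and after the GC and length correction. The interferon response list lies highest in both, at 0.58 and 0.51.

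Among metabolic lists, glycolysis genes (21 tested) had a median of 0.25 (adjusted p = 0.141), which passed with the replicate block (0.0257) and without miR-125b replicate 1 (0.0166), and not with block and correction (0.0746). Its median was 0.11 without control replicate 1, 0.14 without miR-125b replicate 2 and 0.089 after the correction, and the list had adjusted p = 0.985 with an estimated correlation. PKM, PFKL, GPI and PFKP had log2 fold changes of 0.34, 0.58, 0.34 and 0.45. Nuclear subunits of oxidative phosphorylation (73 tested) had a median of -0.12 (adjusted p = 0.716), which was -0.10 after the correction and passed only with block and correction (adjusted p = 0.0328), against adjusted p = 0.879 with an estimated correlation after the correction. Without control replicate 1 it was 0.013. ATP5F1E and ATP5F1C were at -0.44 each, and ATP5F1D and NDUFA11 at 0.75 and 0.64. Cholesterol synthesis genes (24 tested) had a median of -0.06 (adjusted p = 0.640), with CYP51A1 at -0.66, IDI1 at -0.55, HMGCS1 at -0.38 and ACAT2 at -0.38. Hypoxia response genes (16 tested) had a median of -0.11 (adjusted p = 0.716), with MXI1 at -0.45, ERO1A at -0.50, PFKFB4 at 0.55 and SLC2A1 at 0.37. With the replicate block limma called 7 glycolysis genes higher and 1 lower, 9 oxidative phosphorylation genes higher and 14 lower, and 3 cholesterol synthesis genes higher and 6 lower. All 12 members of these lists named here were among them, as was ERO1A of the hypoxia list (adjusted p from 0.00373 to 0.0418), and none was called with block and correction. After the correction ACAT2 was still at -0.35 and CYP51A1 at -0.46, while ATP5F1D was at 0.21, ATP5F1E at -0.15 and PFKL at 0.25.

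For stress and signalling, NF-kB and inflammatory targets (24 tested) had a median of 0.09 (adjusted p = 0.836), with CCL20 at -1.05, CXCL8 at -0.42, NFKBIB at 0.35 and SOD2 at 0.40. Immediate early genes (29 tested) had a median of -0.06 (adjusted p = 0.969), with DUSP6 at -0.49, MCL1 at -0.52, DUSP5 at -0.61 and KLF6 at -0.53. The direction of the NF-kB list turned without control replicate 1, where both of these lists passed, with medians of -0.11 and -0.10 and adjusted p = 0.0388 and 0.00356. Over all 4 libraries both had adjusted p = 0.985 with an estimated correlation. Unfolded protein and integrated stress response genes (32 tested) had a median of 0.08 (adjusted p = 0.532), with PHGDH at 0.64, VLDLR at 0.70, CRELD2 at 0.97 and SDF2L1 at 0.41. Without miR-125b replicate 2 this list passed, with a median of 0.13 and adjusted p = 0.0181, against adjusted p = 0.985 over all 4 libraries with an estimated correlation. MicroRNA machinery genes (19 tested) had a median of -0.06 (adjusted p = 0.836), with MOV10 at 0.60, LIN28B at -0.44, DGCR8 at 0.30 and DDX5 at -0.31. Autophagy and lysosome genes (37 tested) had a median of -0.0025 (adjusted p = 0.716), or 0.026 with median-of-ratios size factors, and CTSD at 0.53, GABARAPL2 at -0.44, GABARAPL1 at -0.59 and ATG4A at -0.54. With the replicate block limma called CCL20, DUSP6, MCL1, KLF6, PHGDH, VLDLR, SDF2L1, MOV10, DDX5 and the 4 autophagy and lysosome genes of those named here (adjusted p from 0.00931 to 0.0453), and none with block and correction. After the correction DUSP6 was at -0.47, GABARAPL1 at -0.56 and VLDLR at 0.88, while CTSD was at 0.18 and SDF2L1 at -0.018.

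Markers of other cell types were mostly below the filter. Of the T and NK cell markers 5 of 18 were tested (median 0.18, adjusted p = 0.640), with NCAM1 at 0.36, CD4 at 0.31, CD3D at -0.21 and PRF1 at 0.18. Of the epithelial and fibroblast markers 3 of 16 were tested (median 0.15, mean -0.035, adjusted p = 0.969; median -0.12 after the correction), with EPCAM at -0.68, FN1 at 0.43 and KRT18 at 0.15. EPCAM was called with the replicate block (adjusted p = 0.0354) and not with block and correction, where it was at -0.58. The B cell markers (2 of 13 tested), the erythroid and megakaryocyte markers (2 of 20) and the replication-dependent histones (2 of 14) had too few tested members for a test. CD79B and CD79A were at 0.60 and 0.29, EPOR and ITGA2B at -0.46 and 0.56, and the histones H2BC12 and H4C8 at 0.23 each. The mitochondrially encoded mRNAs had no rows among those analysed here.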

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

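The alternatives were run with limma on RPKM; the edgeR fit, DESeq2 and TMM factors need counts and were not run, and scaling by total reads alone is already the RPKM scaling. Quantile normalization, the pseudocounts, the sum of a gene's rows and the correction for GC content and length were chosen after seeing the data. The count of 0 called genes held with median-of-ratios size factors, no filter, the stricter filter, both looser and 2-fold thresholds, quantile normalization, both pseudocounts, summed rows and the correction, alone or with the block. limma-voom called 4 genes (2 higher, 2 lower), and the replicate block 1429 (773 higher, 656 lower). Leaving out a library gave 0 to 2149 genes, 0 to 1176 higher and 0 to 973 lower: 101 without control replicate 1, 2149 without control replicate 2 and 0 without either miR-125b library. The remaining single library of a group was assumed to vary like the other group. For the block, simulated GC trends raised the false calls, to at most 54 with no gene changed and 448 with 200 changed, which is below 1429; the cause was not tested for the rest nor for the other settings.

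The number of lists past the threshold was 2 and stayed so with median-of-ratios size factors, quantile normalization, the stricter filter and both pseudocounts. It was 4 with the replicate block, 4 with block and correction, 0 with an estimated correlation, 0 with an estimated correlation after the correction and 0 with fry, and 2 to 4 when a library was left out. The correction also left 2 lists, but these were the interferon response and the published targets. fry tests a list against no change rather than against other genes, so its p is not a repeat of the camera call. With an estimated correlation every tested list had adjusted p = 0.985 as deposited (camera in limma). The adjusted p of a call lost in that setting therefore does not set its list apart from the others. The estimated correlation itself did differ between lists. It was highest for the interferon list, at 0.556 as deposited and 0.675 after the correction. For the primary granule list it was 0.102 and 0.388. All of these lie above the preset correlation, so correlation between members may contribute to the loss of these calls. The interferon list lost its call with an estimated correlation (median 0.58, adjusted p = 0.985) and with that and the correction (median 0.51, adjusted p = 0.879), and did not pass fry (0.58, adjusted p = 0.745); its median was 0.19 to 0.81 when a library was left out. The primary granule list lost its call with an estimated correlation (0.22, adjusted p = 0.985) and after the correction (0.12, adjusted p = 0.123, or 0.879 with an estimated correlation), and did not pass fry (0.22, adjusted p = 0.745); its median was 0.18 to 0.27 when a library was left out. The cause was not tested. Without the correction the block changed no other list's call than those of the retinoic acid and glycolysis lists; added to the correction it changed those of the primary granule (adjusted p = 0.123 to 0.0498) and oxidative phosphorylation (0.123 to 0.0328) lists.

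The medians of 12 of the 23 lists reported here changed sign in some setting, all of them lists that did not pass as deposited. After the correction, with or without the block or an estimated correlation, S phase was at 0.019, G2/M at 0.029, the mature neutrophil and monocyte list at -0.061, NF-kB at -0.073 and the epithelial and fibroblast list at -0.12. With median-of-ratios size factors S phase was at 0.0018, ribosome biogenesis at 0.013 and autophagy at 0.026, and with quantile normalization autophagy was at 0.011. When a library was left out, medians ranged from -0.14 to 0.087 for caspases, -0.11 to 0.028 for S phase, -0.091 to 0.21 for mature neutrophil and monocyte genes, -0.12 to 0.30 for NF-kB, -0.13 to 0.16 for immediate early genes, -0.043 to 0.13 for the unfolded protein response, -0.22 to 0.013 for oxidative phosphorylation, -0.094 to 0.018 for ribosomal proteins, -0.062 to 0.044 for ribosome biogenesis and -0.11 to 0.40 for epithelial and fibroblast markers. Of 1627 values of 109 named genes under alternatives, 18 changed sign. After the correction, with or without the block, BAK1 was at -0.14, NFKBIB at -0.034, SDF2L1 at -0.018, BOP1 at -0.0024, H2BC12 at -0.074, PRF1 at -0.051 and KRT18 at -0.12. When a library was left out BAK1 ranged from -0.041 to 0.18, H4C8 from -0.0085 to 0.47 and KRT18 from -0.11 to 0.40. The cause was not tested.

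The difference for seed site genes, 0.053, was 0.088 for 7mer-m8 or 8mer sites, past the threshold only before adjustment over 4 site definitions. It changed sign to -0.016 with a matched background, to -0.022 with that and the correction, to -0.031 for matched 8mer sites after the correction, to -0.0067 for 8mer sites after the correction and to -0.0011 with the shortest 3' UTR after the correction; it was -0.0011 to 0.091 when a library was left out. The percentile of CTCAGGG, 1.31, was 51.96 with the shortest 3' UTR (0.00616 with that and the correction) and 94.3 with no trend removed, and 0.287 to 9.70 when a library was left out; the cause was not tested. Depth limits weakly expressed genes most in control replicate 1, where 41.9% of rows were at 0 against 34.2% in miR-125b replicate 2.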

Other observations

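The tests in this part were chosen after the result was seen, except 3 on seed matches: the share of sites at the extremes, the difference between batches, and each batch taken alone. The settings without a library, with an estimated correlation and with the shortest 3' UTR before the correction had also been fixed earlier.

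GC-rich transcripts were higher in the miR-125b libraries. The difference between the 2 miR-125b libraries, which share a treatment, also followed GC content (r = 0.502 across genes), so a library bias is a candidate source of the trend. The lower depth of control replicate 1 alone is argued against by the pair of near-equal depth, miR-125b replicate 1 and control replicate 2, where r was 0.232. The gap between the bins of highest and lowest GC content was 0.679 and 0.628 between treatments within the batches, larger than between replicates (0.465 and 0.397), but 0.224 between miR-125b replicate 1 and control replicate 2. An effect of the precursor on GC-rich genes cannot be told apart from library bias with 2 libraries per group.

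Interferon response genes were higher in both batches. GC content bias as the whole source is argued against by a median of 0.51 after the correction, and miR-125b replicate 2 as the only source by a median of 0.19 without it, although that library carried most of the rise. A shift shared by both libraries of a batch cancels between the groups, so by design it cannot give the rise. The batch medians therefore do not test it. The medians between treatments were 0.29 in batch 1 (28 of 36 genes above 0) and 0.84 in batch 2. The batches differed by 0.025 in the controls and 0.58 in the miR-125b libraries, so variation between single libraries stays open. The list had adjusted p = 0.985 with an estimated correlation (camera in limma), which was 0.556 between its members, above the preset value. Its members therefore count for less than separate genes in that test. The smaller of the corrected medians of the batches was 0.27, so a response to the miR-125b precursor, whether to its sequence or to how the duplex was delivered, may contribute. It stays open because each group held only its own precursor, in 2 libraries. The miR-125b sequence therefore cannot be told apart from other differences between the transfections. No library with another precursor, or without any, was analysed here.

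Matches to the miR-125b seed may mark a small decrease that the GC trend masked: CTCAGGG stood at percentile 0.0122 of the 7-mers after the correction, against 1.31 before it. In the difference between batches CTCAGGG stood at percentile 10.1, which argues against leftover sequence composition that follows the batches. Treatment cancels from that difference, so composition that follows the groups, as GC content did (r = 0.637), stays open. A single batch as the source is argued against by percentiles of 0.116 and 0.104 in the batches taken alone. The more direct tests compared genes, which are not independent replicates, and were divided. After the correction, genes with a site differed by -0.022 (permutation p = 0.00739) from genes matched on 3' UTR length and GC content. Those with an 8mer differed by -0.031 (permutation p = 0.00772). The set had adjusted p = 0.906 (camera in limma) against unmatched genes, whose 3' UTRs are shorter (median 881 against 2554 bases). The permutation allows for no correlation between genes, while camera took a preset 0.01, estimated at 0.00033 after the correction. Of the 200 genes with the lowest corrected statistic 55 held a site, against 41 of the 200 with the highest and 24.9% of all genes. The odds ratio was 1.47 (95% interval 0.903 to 2.41, Fisher's exact p = 0.128). That test did not match 3' UTR length, whose median was 835 bases at the low end and 1059 at the high end. A decrease of mRNAs with a seed match therefore stays open, and with the shortest 3' UTR the percentile was 51.96 before the correction and 0.00616 after it.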
